A study of Rattus norvegicus with 10 samples.

How the data were processed

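Total RNA from the liver of female Harlan Sprague-Dawley rats was measured in 10 samples, 5 given corn oil and 5 given I3C at 300 mg per kg by gavage, 5 days per week. Per the labels, dosing lasted 13 weeks, tissue was frozen in liquid nitrogen at collection, and RNA was extracted on silica columns and checked by absorbance and gel electrophoresis. Per the labels' protocols, 5 ug of total RNA was converted by 3' one-cycle amplification to biotin-labelled antisense RNA and hybridised to rat whole-genome GeneChip arrays.

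The table used here holds the authors' deposited log2 expression values, made with RMA, the robust multi-array average, per the submitters' processing notes. The version of RMA and the software that ran it are not given in the sources used here. RMA pulls the distributions of the arrays together and compresses large folds, so that a shift common to all genes is removed and folds of bright probe sets can be understated. The values ranged from 3.00 to 15.1 and the medians of the arrays from 6.21 to 6.29. Correlations between pairs of arrays ran from 0.983 to 0.997, and the SD of the difference between any pair was at least 0.17, so that no array was a copy of another. The table holds 31099 probe sets, of which 57 are the manufacturer's controls and served only as quality measures.

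Probe sets were named through the platform annotation of 2016, with symbols taken by Entrez ID from a RefSeq gene table on assembly GRCr8, which was used for names only. In this way 20758 probe sets took their symbol, whether or not it differed from that of 2016. Of 31042 probe sets, 20826 carry 1 gene, 436 several and 9780 none here, and none with several was used for a gene. Each of 14217 genes was followed through the probe set with the highest mean over all 10 arrays. Fixed gene lists, 36 in number, held 856 symbols, of which 756 matched a measured gene, 11 of them through an older symbol.

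Dosed and vehicle arrays were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without trend, prior degrees of freedom 4.60), two-sided, with Benjamini-Hochberg adjustment over the 31042 probe sets and a threshold of 0.05. "Rose" and "fell" are used for genes past that threshold, and ± after a difference is its SE from this fit. Counts adjusted over the list alone repeat the adjustment within a list. Lists were tested with camera at a preset correlation of 0.01 between genes, adjusted over the 36 lists. Of 19 lists called this way, 8 up and 11 down, 4 were also called with a correlation estimated for each list: the aryl hydrocarbon receptor targets, the NRF2 targets, conjugation, and endoplasmic reticulum stress and amino acid response. With an estimated correlation camera also takes its degrees of freedom from the arrays rather than from the genes. A call lost there need not come from correlation between genes. The self-contained test fry, which asks whether the genes of a list move one way without comparing them to other genes, called 17. Single values per array were compared by exact permutation tests over the 252 ordered splits, two-sided, with adjustment over the 17 measures.

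The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 15 largest rises and 15 largest falls among genes past the threshold whose groups do not overlap, and up to 4 members of each list by size among those past the threshold, or the 2 brightest members where fewer than 2 passed. It adds Cyp1a1, Cyp1a2, Cyp1b1, Cyp2b1, Cyp3a23-3a1, Cyp7a1, Cyp2c11, Cyp2c12, Nqo1, Gstp1, Mki67 and Alb where measured, and gave 120 genes.

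The alternatives fixed in advance were another variance model, the replicate number as a block, a filter on dim probe sets, renewed quantile normalisation, median centring, array weights, no moderation of the variance, a stricter threshold, other size limits, the mean of a gene's probe sets, the other list tests, and leaving out each array in turn. The 3' minus 5' differences of GAPDH, beta-actin and the dap spike as covariates were added after seeing the data. The fit was tested on simulated arrays with the means and spreads of these samples. For dosed against vehicle over 31042 probe sets it recovered 86.6% of 67 probe sets changed 1.5-fold, 95.5% of 67 changed 2-fold and 98.5% of 66 changed 4-fold, called 10 unchanged probe sets, and called 0 unchanged lists over 14217 genes. The simulated genes varied independently of one another, whereas the estimated correlation reached 0.42 in the macrophage list. The count of 0 lists therefore does not vouch for list calls at the preset correlation. Other splits of the real arrays called a median of 4 lists.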

Results

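Liver RNA was profiled on rat whole-genome 3' expression arrays in 10 liver samples of female Harlan Sprague-Dawley rats, in 2 groups of 5. The dosed rats received indole-3-carbinol (I3C), a compound released from cruciferous vegetables, by gavage in corn oil at 300 mg per kg, 5 days per week. The vehicle rats received corn oil alone, which the labels give as 0 mg per kg. The labels give 13 weeks of dosing for both groups, whereas the design text of the series speaks of a 2-year study, and 13 weeks is given here as the labels state it. The comparison asks which liver transcripts differ under the dose. Each array carries 31042 probe sets outside the manufacturer's controls, and 14217 genes were followed through their brightest probe set. The medians of the arrays lay between 6.21 and 6.29 on the log2 scale. The number of arrays, 5 per group, limits the precision of every value. The labels give no animal numbers, so the p-values measure the spread between these samples.

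Between dosed and vehicle livers 914 of the 14217 genes changed, of which 472 rose and 442 fell, and 101 of these changed at least 2-fold, 65 up and 36 down. Cyp1a1, the cytochrome P450 that responds most to ligands of the aryl hydrocarbon receptor, rose by 8.38 ± 0.15 on the log2 scale (SE, n = 5 per group, limma adjusted p = 5.75e-12). Its mean moved from 5.53 ± 0.40 (SD, n = 5) to 13.91 ± 0.04 (SD, n = 5), a 334-fold difference. That fold rests on a dim vehicle level, at the 37.4th percentile of probe sets. Cyp1b1 of the same family followed at 6.23 ± 0.17 (SE), a 74.8-fold rise. The deepest fall was that of Car3, a cytosolic carbonic anhydrase that is abundant in liver and muscle, at -4.00 ± 0.29 (SE, limma adjusted p = 1.16e-05), a 16.0-fold fall.

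The 15 largest rises reached beyond drug metabolism. They took in Rbm24, an RNA-binding protein (4.89 ± 0.18, SE, from a dim vehicle level of 4.63), Scn4b, a sodium channel subunit (4.10 ± 0.26), and Scd2, a stearoyl-CoA desaturase (4.08 ± 0.51). Asns, which makes asparagine, rose by 3.67 ± 0.22, Trib3, a pseudokinase, by 2.99 ± 0.16, and the probe set annotated to Iars2 by 2.96 ± 0.10. Iars2 is a mitochondrial isoleucyl-tRNA synthetase, and that this probe set measures it rests on the platform annotation alone. Nqo1 (2.85 ± 0.09), Phgdh (2.67 ± 0.20), Fgf21 (2.56 ± 0.24), Aldh3a1 (2.37 ± 0.26), Tsku (2.15 ± 0.13), Tgm1 (2.14 ± 0.22) and Psat1 (2.03 ± 0.17) completed the 15. Among the 15 largest falls, Kcnj15, a potassium channel, lay at -2.76 ± 0.38, the flavin monooxygenase Fmo1 at -2.46 ± 0.14, Serpina7, the thyroxine-binding globulin, at -2.30 ± 0.28, and Cyp3a9 at -2.12 ± 0.28. Cpa1 (-2.10 ± 0.28), Tsc22d1 (-2.01 ± 0.15), Cadps (-2.00 ± 0.30), Hao2 (-1.96 ± 0.28), Sez6 (-1.93 ± 0.24), Mtmr7 (-1.83 ± 0.23), Nrep (-1.79 ± 0.42), Slc13a3 (-1.66 ± 0.18), Inhba (-1.65 ± 0.18) and Slc34a2 (-1.64 ± 0.27) followed. Of several probe sets of Rbm24, Kcnj15, Tsc22d1, Cadps and Inhba, only the one given passed, and the others of Rbm24 differed by 0.05 to 0.21. For Nrep the call ended when vehicle 3, dosed 1, dosed 2 or dosed 5 was left out, with adjusted p between 0.0614 and 0.0755.

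These calls come from limma, with Benjamini-Hochberg adjustment over all 31042 probe sets. Over all 14217 genes, changed or not, 1233 had no overlap between dosed and vehicle arrays, which is 8.67% where chance gives 0.794%, and 803 of these were among the 914. Of the 312 changed genes with several probe sets, 124 had at least 2 probe sets called the same way and 0 had one called the other way.

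A measure of RNA quality also differed between the groups. The 3' minus 5' difference of the GAPDH control probe sets was 0.45 ± 0.12 (SD, n = 5) in vehicle arrays and 0.23 ± 0.05 (SD, n = 5) in dosed arrays, and all 5 dosed arrays were lower than every vehicle array. The exact permutation p (two-sided) was 0.00794, the smallest that 5 against 5 can give, and 0.0337 after adjustment over 17 array measures. For beta-actin the same difference was 1.59 ± 0.12 (SD, n = 5) against 1.40 ± 0.14 (SD, n = 5), with an exact permutation p of 0.0476 and 0.116 after adjustment. The 17 measures also hold the first principal component and the medians of the macrophage, interferon, endothelial and NRF2 lists, which are drawn from the expression values compared here. The low p of these measures lowers the adjusted values, so neither value holds for quality measures alone. When the GAPDH difference entered the model as a covariate, an alternative chosen after seeing the data, 228 genes were changed, of which 190 were among the 914, and all 914 kept their sign. Of the 724 genes whose call ended, 471 kept at least 75% of their change, 161 kept 50% to 75% and 92 kept less. Of the 15 largest rises 14 were still called and of the 15 largest falls 12, the exceptions being Scd2 (3.65 ± 0.85), Cpa1 (-2.03 ± 0.48), Nrep (-1.61 ± 0.72) and Slc34a2 (-1.59 ± 0.46), which lay close to their sizes without the covariate. Vehicle 5 stood apart from the other vehicle arrays on the second principal component, and without it 1243 genes were changed, of which 544 rose and 699 fell.

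**Figure D1:**
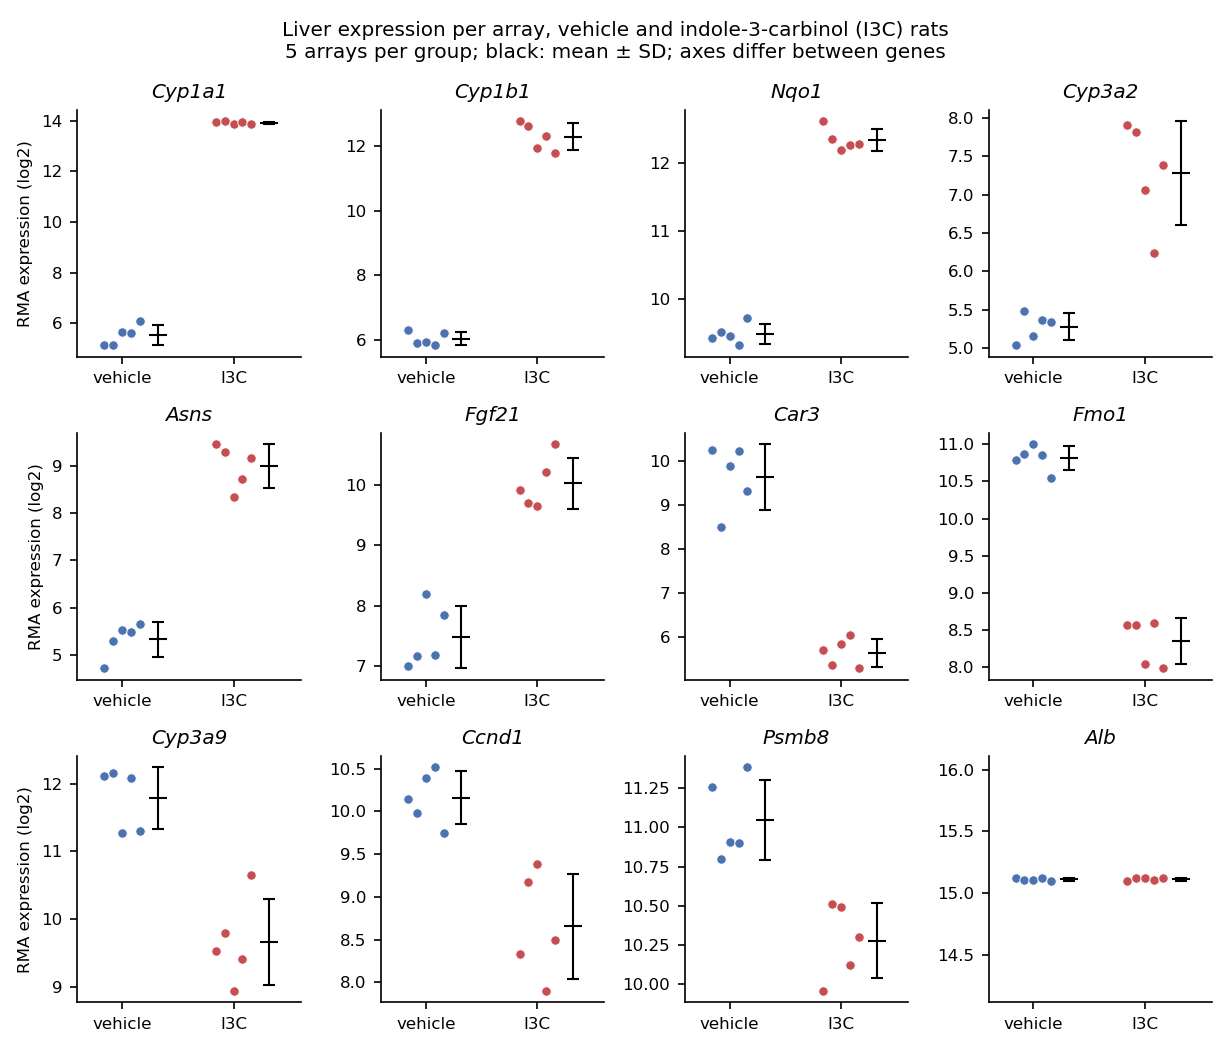
RMA expression on the log2 scale (vertical axis, different for each gene) of 12 genes in the 5 vehicle and 5 I3C arrays; each point is 1 array and black marks give mean ± SD. Cyp1a1 moves from a vehicle mean of 5.53 to a dosed mean of 13.91, Car3 from 9.64 to 5.64, and albumin (Alb) lies at 15.11 in both groups.

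Most measured targets of the xenobiotic sensors rose in the dosed livers. Of 14 measured aryl hydrocarbon receptor targets 8 rose and 2 fell, with 9 and 2 when adjusted over the list alone. Besides Cyp1a1 and Cyp1b1, Nqo1, a quinone reductase, rose 7.21-fold. Cyp1a2, already at 13.58 ± 0.26 (SD, n = 5) in vehicle livers, rose by 1.11 ± 0.11 (SE). Fmo1 and Lrat (-0.51 ± 0.10), which esterifies retinol, were the 2 members that fell. Of 26 targets of NRF2, the transcription factor of the antioxidant response, 18 rose and 0 fell, and 21 rose when adjusted over the list alone. Akr1b8, an aldo-keto reductase, rose by 1.98 ± 0.27, the organic anion exporter Abcc3 by 1.93 ± 0.17 and malic enzyme Me1 by 1.89 ± 0.12.

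Of 19 targets of the nuclear receptors CAR and PXR 12 rose and 1 fell, with 12 and 2 when adjusted over the list alone. Cyp3a2 rose by 2.00 ± 0.25 from a low level of 5.28 ± 0.18 (SD, n = 5), Por, the reductase that passes electrons to P450 enzymes, by 1.32 ± 0.12, and Cyp3a23-3a1 by 0.77 ± 0.16, while Cyp3a9 fell, and 2 members fell without vehicle 5. Cyp2b1 was not measured alone: the probe set annotated to it together with 1 other CYP2B enzyme rose by 5.02 ± 0.28 (SE, limma adjusted p = 8.03e-07), and was singled out after its value was seen. Camera, a competitive gene set test, called all 3 lists as shifted up: aryl hydrocarbon receptor targets at an adjusted p of 1.16e-10, NRF2 targets at 4.83e-26 and CAR and PXR targets at 9.89e-09. The adjusted p was 0.00376, 0.00196 and 0.12 with an estimated correlation, so that the call of the CAR and PXR list was lost. Some genes stand in more than 1 of these lists, such as Nqo1 (aryl hydrocarbon receptor and NRF2) and Abcc3 (NRF2, and CAR and PXR). The 3 calls are therefore not independent of one another. In the model with the GAPDH difference 6 aryl hydrocarbon receptor targets rose and 1 fell, 11 NRF2 targets rose, and 6 CAR and PXR targets rose and 1 fell. The calls of Akr1b8 (1.77 ± 0.46 there, adjusted p = 0.107) and Lrat (-0.53 ± 0.16, adjusted p = 0.164) ended at nearly the same size, and that of Cyp3a23-3a1 ended at a much smaller one (0.19 ± 0.18, adjusted p = 0.645).

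Conjugating enzymes were shifted up as a group, and P450 enzymes outside the induced subfamilies mostly did not pass. Of 32 transferases of glutathione, glucuronic acid and sulfate conjugation 12 rose and 1 fell, with 14 and 3 when adjusted over the list alone. The glutathione transferases Gsta3 (1.62 ± 0.16), Gstm3 (1.20 ± 0.18) and Gsta4 (1.08 ± 0.08) and the glucuronosyltransferase Ugt2b1 (1.28 ± 0.11) led the list. The fallen member was Sult1a1, a sulfotransferase (-0.40 ± 0.10), and 0 fell without vehicle 1, vehicle 2, dosed 1, dosed 3 or dosed 5, and 2 without vehicle 4 or vehicle 5. Of 25 other P450 enzymes 1 rose and 5 fell, with 3 and 8 when adjusted over the list alone: the steroidogenic Cyp17a1 fell by 1.27 ± 0.24, Cyp2e1 by 0.33 ± 0.06, and Cyp2a1 rose by 0.52 ± 0.08. Camera called conjugation as shifted up (adjusted p = 9.89e-09, and adjusted p = 0.0481 with an estimated correlation). It called the other P450 enzymes as shifted down at an adjusted p of 0.0315, which was 0.12 with an estimated correlation, 0.0615 without vehicle 1, 0.0522 without vehicle 2 and 0.246 with the beta-actin difference in the model, an alternative also chosen after seeing the data. With 1 array left out, 7 of these P450 enzymes fell without vehicle 5, 4 without vehicle 2, and 2 or 3 without any other array. With the GAPDH difference in the model 7 conjugating enzymes rose, 0 of the other P450 enzymes passed limma (1 higher and 6 lower at an unadjusted p under 0.05), and the call of Gstm3 ended at 1.24 ± 0.30 (adjusted p = 0.0861). Cyp17a1 (-1.37 ± 0.40), Cyp2e1 (-0.36 ± 0.10) and Cyp2a1 (0.54 ± 0.13) had about the same size there as without it.

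Some genes of the amino acid response rose, and some of amino acid breakdown fell. Of 24 genes of endoplasmic reticulum stress and the amino acid response 7 rose and 0 fell, with 8 rising when adjusted over the list alone. Asns rose 12.7-fold, from a dim vehicle level of 5.33 at the 33.9th percentile of probe sets, and Trib3 rose 7.95-fold. Dnajb9, a co-chaperone, rose by 0.82 ± 0.09, and Atf4, the transcription factor that drives Asns and Trib3 when amino acids are short, by 0.75 ± 0.08. Phgdh and Psat1, which stand at the head of serine synthesis, were in no fixed list and rose 6.36-fold and 4.09-fold. Of 37 genes of amino acid catabolism and the urea cycle 1 rose and 7 fell, with 2 and 13 when adjusted over the list alone. Gls2, the liver glutaminase, fell by 0.87 ± 0.10, Uroc1 and Hal of histidine breakdown by 0.80 ± 0.08 and 1.10 ± 0.24, and Tat, tyrosine aminotransferase, rose by 0.93 ± 0.16. Camera called the stress list as shifted up (adjusted p = 9.60e-09, and adjusted p = 0.0325 with an estimated correlation) and the breakdown list as shifted down (adjusted p = 0.00166, and adjusted p = 0.149 with an estimated correlation). The call of Hal ended without vehicle 1 (adjusted p = 0.0547) or vehicle 3 (adjusted p = 0.0517), and 4 breakdown genes fell without vehicle 1. In the model with the GAPDH difference 4 genes of the stress list rose and 4 of the breakdown list fell, and the calls of Hal (-1.06 ± 0.41, adjusted p = 0.266) and Tat (0.53 ± 0.24, adjusted p = 0.324) ended.

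In glucose metabolism 2 of 22 genes rose and 7 fell, with 3 and 10 when adjusted over the list alone. Pfkfb1, which sets the level of fructose 2,6-bisphosphate, rose by 1.31 ± 0.12, and Irs2, an insulin receptor substrate, fell by 0.71 ± 0.16. The list was called as shifted down (camera adjusted p = 0.00322), a call lost with an estimated correlation (adjusted p = 0.149). Its number of fallen genes was 3 without dosed 4 and 4 without vehicle 2, vehicle 3, dosed 1 or dosed 2, and Irs2 lost its call without dosed 2 (adjusted p = 0.0558) or dosed 4 (adjusted p = 0.054). Igfbp1, the other risen gene (1.20 ± 0.30), lost its call without vehicle 3, vehicle 4, vehicle 5, dosed 2, dosed 3, dosed 4 or dosed 5 (adjusted p up to 0.106). With the GAPDH difference in the model 1 gene of the list rose and 1 fell, Igfbp1 went from 1.20 to 0.15 ± 0.35 (adjusted p = 0.868), and Irs2 lay at -0.57 ± 0.26 (adjusted p = 0.335).

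Of the 4 lists of lipid genes camera called those of cholesterol and bile acids, and few members of any passed. Of 36 PPAR alpha targets and fatty acid oxidation genes 3 rose and 5 fell (5 and 6 when adjusted over the list alone, camera adjusted p = 0.37): Fgf21, a hormone of fasting, rose 5.89-fold and Pdk4, which restrains pyruvate oxidation, by 0.82 ± 0.17, while Angptl4 fell by 0.53 ± 0.10. This list was called as shifted down with the GAPDH difference in the model (camera adjusted p = 0.0032, against 0.178 to 0.836 under the alternatives fixed in advance), and 3 of its genes were higher and 13 lower at an unadjusted p under 0.05, against 8 and 7 without it. Of 25 genes of fatty acid and triglyceride synthesis 1 rose and 3 fell (6 and 5 when adjusted over the list alone, camera adjusted p = 0.852), with Srebf1, the lipogenic transcription factor, at -0.62 ± 0.13 and Dgat2 at -0.49 ± 0.09. The risen gene was Me1 (1.89 ± 0.12), also an NRF2 target. The desaturase Scd2, which rose by 4.08 ± 0.51, was not in this list. Of 22 genes of cholesterol synthesis and uptake 2 rose and 0 fell (4 and 0 when adjusted over the list alone). Both risen genes, Insig1 (0.88 ± 0.15) and Insig2 (0.57 ± 0.09), are known to restrain the pathway. The list was called as shifted up at a camera adjusted p of 0.00166, and neither with an estimated correlation (adjusted p = 0.347) nor with the GAPDH difference (adjusted p = 0.147). Of 25 genes of bile acid synthesis and transport 3 rose and 4 fell (4 and 11 when adjusted over the list alone). Nr0b2, a repressor of bile acid synthesis, rose by 1.17 ± 0.16, the sterol 12-hydroxylase Cyp8b1 fell by 0.70 ± 0.15 and the bile acid receptor Nr1h4 by 0.54 ± 0.10. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, differed by -1.07 ± 0.32 and did not pass (adjusted p = 0.0887). The bile acid list was called as shifted down at a camera adjusted p of 0.0431, and neither with an estimated correlation (adjusted p = 0.37) nor with the beta-actin difference (adjusted p = 0.0919). It also lost the call without vehicle 2, vehicle 4, dosed 1 or dosed 2, at adjusted p of 0.12, 0.10, 0.0899 and 0.0704, and 7 of its genes fell without vehicle 5. Without dosed 2, 3 PPAR alpha targets fell, without vehicle 4, 4 cholesterol genes rose, and without vehicle 5, 2 genes of fatty acid and triglyceride synthesis rose. Of the lipid genes named here, Fgf21, Me1 and Nr1h4 kept their calls with the GAPDH difference in the model, where Srebf1 went to -0.29 ± 0.19, Insig2 to 0.38 ± 0.14 and Dgat2 to -0.33 ± 0.13. Scd2 (3.65 ± 0.85), Pdk4 (0.68 ± 0.28), Angptl4 (-0.72 ± 0.16), Insig1 (0.82 ± 0.26), Nr0b2 (0.87 ± 0.24) and Cyp8b1 (-0.58 ± 0.26) lost their calls there too.

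Sex-dependent genes did not move as a block from the female to the male pattern. Cyp2c12, the main female-specific P450 of rat liver, was 14.19 ± 0.04 (SD, n = 5) in vehicle and 14.10 ± 0.09 (SD, n = 5) in dosed livers (adjusted p = 0.591). Cyp2c11, its male counterpart, was 6.12 ± 0.09 (SD, n = 5) and 6.16 ± 0.09 (SD, n = 5) (adjusted p = 0.897). Of 12 genes listed as female-predominant 1 rose and 4 fell (2 and 5 when adjusted over the list alone), led by Fmo1, which also stands among the aryl hydrocarbon receptor targets, and Cyp17a1. All rats were female, so that these genes, Fmo1 among them, are female-predominant rests on the fixed list and was not tested. A fall in this list is thus not in itself a loss of the female pattern. The list was called as shifted down (camera adjusted p = 0.012), and not with an estimated correlation (adjusted p = 0.229), the GAPDH difference (adjusted p = 0.0745) or the beta-actin difference (adjusted p = 0.062). Its number of fallen genes was 2 without vehicle 2, vehicle 4, dosed 1 or dosed 4, and 1 with the GAPDH difference in the model, where the call of Cyp17a1 ended at -1.37 ± 0.40 (adjusted p = 0.146). Of 17 male-predominant genes 2 rose and 2 fell (2 and 4 when adjusted over the list alone, camera adjusted p = 0.719): Car3 and Hao2 fell, and Cyp3a2 and the hydroxysteroid dehydrogenase Akr1c1 (0.72 ± 0.14) rose. The call of Akr1c1 ended with the GAPDH difference in the model, at 0.28 ± 0.18 (adjusted p = 0.501).

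Among zonation markers camera called the periportal list as lower and did not call the pericentral list. Of 16 periportal genes 0 rose and 3 fell (0 and 8 when adjusted over the list alone), with Gls2, Cdh1, the cadherin of epithelial junctions (-0.41 ± 0.07), and Hal, whose call rests on vehicle 1 and vehicle 3 (adjusted p = 0.0547 and 0.0517 without them). With the mean of its probe sets the call of Cdh1 ended (-0.16, adjusted p = 0.0967). The list was called as shifted down (camera adjusted p = 6.21e-05), and not with an estimated correlation (adjusted p = 0.122). Of 15 pericentral genes 4 rose and 3 fell (5 and 6 when adjusted over the list alone, camera adjusted p = 0.436). Cyp1a2, Tbx3 (0.92 ± 0.17) and Aldh1a1 (0.80 ± 0.17) rose. Of these, Cyp1a2 also stands among the aryl hydrocarbon receptor targets and Aldh1a1 among the CAR and PXR targets. The largest fall in the list was that of Slc13a3 (-1.66 ± 0.18), and Glul, the glutamine synthetase of the cells next to the central vein, fell by 0.98 ± 0.13. With the GAPDH difference in the model 1 periportal gene fell, and 1 pericentral gene rose and 1 fell; the calls of Cdh1 (-0.30 ± 0.11), Tbx3 (0.34 ± 0.18), Aldh1a1 (0.36 ± 0.24) and Glul (-0.85 ± 0.21) ended.

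Proliferation genes and markers of preneoplastic foci gave separate pictures. Of 33 cell cycle and DNA replication genes 0 rose and 1 fell, the same when adjusted over the list alone. Ccnd1, cyclin D1, fell 2.84-fold (limma adjusted p = 0.00376) and was called by all 3 of its probe sets. The proliferation marker Mki67 differed by -0.21 ± 0.10 (adjusted p = 0.316) and Pcna by 0.15 ± 0.09 (adjusted p = 0.5). The cell cycle list was called as shifted down at a camera adjusted p of 0.0432, and not with an estimated correlation (adjusted p = 0.37) nor without vehicle 2, vehicle 4, vehicle 5, dosed 1, dosed 2 or dosed 5 (adjusted p between 0.0801 and 0.125). That call also ended with the GAPDH difference (adjusted p = 0.162) and with the dap spike difference (adjusted p = 0.0881). Of 17 markers of altered hepatic foci 4 rose and 0 fell (6 and 0 when adjusted over the list alone): Aldh3a1, Akr1b8, Abcc3 and the aflatoxin reductase Akr7a3 (2.82-fold), all of which also stand in the lists of aryl hydrocarbon receptor or NRF2 targets. Gstp1, the classic marker of such foci, differed by 0.79 ± 0.25 and did not pass (adjusted p = 0.109). Dosed 5 lay far above the other dosed arrays, and without it Gstp1 differed by 0.50 and passed (adjusted p = 0.026). The foci list was called as shifted up (camera adjusted p = 7.04e-04), and not with an estimated correlation (adjusted p = 0.0568). Of 19 p53 targets 4 rose and 1 fell (6 and 3 when adjusted over the list alone), with Gadd45a at 1.67 ± 0.17, Gadd45b at 1.00 ± 0.09 and the DNA repair gene Ddb2 at 0.71 ± 0.07. The other probe set of Ddb2 lay at -0.20 and did not pass. The fallen member, Cdkn1a (-0.80 ± 0.20), an inhibitor of the cell cycle, lost its call without any 1 array other than vehicle 4 and dosed 4 (adjusted p between 0.0557 and 0.097). The p53 list was called as shifted up at a camera adjusted p of 0.00755, and not with an estimated correlation (adjusted p = 0.0696). With the GAPDH difference in the model the call of Ccnd1 ended at -1.41 ± 0.43 (adjusted p = 0.159) and that of Cdkn1a at -0.77 ± 0.34, 3 foci markers and 4 p53 targets rose, and 0 p53 targets fell.

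**Figure D2:**
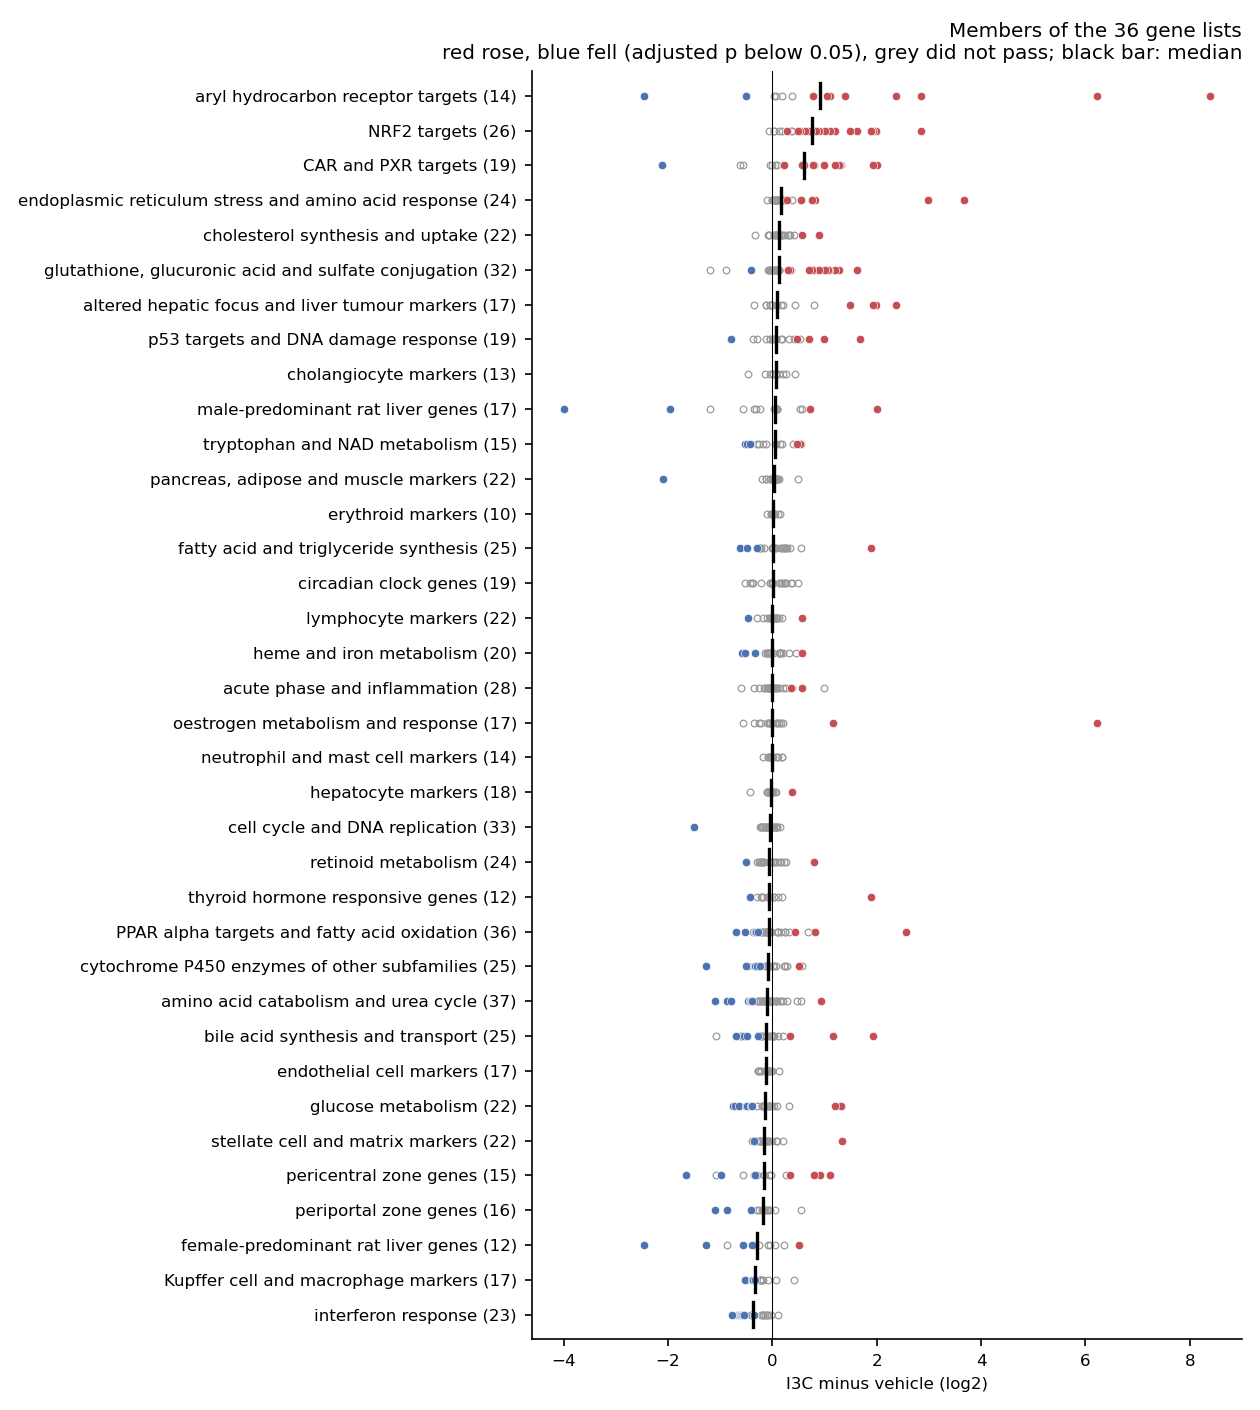
Difference between I3C and vehicle arrays on the log2 scale (horizontal axis) for every measured member of the 36 fixed gene lists, sorted by median, with the number of members in brackets; red points rose, blue points fell, grey circles did not pass, and black bars are medians. The medians run from -0.37 for interferon response genes to 0.91 for aryl hydrocarbon receptor targets.

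The medians of interferon genes and macrophage markers were lower in the dosed livers. Of 23 interferon response genes 0 rose and 8 fell, with 15 falling when adjusted over the list alone. Psmb8 and Tap1, which process and carry peptides for antigen presentation, fell by 0.77 ± 0.13 and 0.61 ± 0.11, and Irf7, an interferon regulatory factor, by 0.60 ± 0.12. The other probe set of Tap1 differed by 0.04, and with the mean of its probe sets the call of Tap1 ended (-0.29, adjusted p = 0.0748). Of 17 markers of Kupffer cells and other macrophages 0 rose and 4 fell, with 1 and 11 when adjusted over the list alone; C1qa, a complement subunit made by Kupffer cells, fell by 0.37 ± 0.08, a call that ended without vehicle 1 (adjusted p = 0.0525) or dosed 5 (adjusted p = 0.0516). The per-array median of the interferon list was lower in dosed arrays by 0.34 (exact permutation p = 0.0159) and that of the macrophage list by 0.28 (exact permutation p = 0.00794). Of 17 endothelial markers 0 rose and 0 fell by limma, also when adjusted over the list alone (0 higher and 3 lower at an unadjusted p under 0.05), and their per-array median was lower by 0.12 (exact permutation p = 0.0159). Camera called the interferon, macrophage and endothelial lists as shifted down at adjusted p of 9.60e-09, 1.51e-05 and 0.0223. The adjusted p was 0.122, 0.255 and 0.126 with an estimated correlation, which ended all 3 calls. The GAPDH 3' minus 5' difference was lower in the same dosed arrays, and 0 genes of the 3 lists passed limma with it in the model, where 5 interferon genes, 6 macrophage markers and 4 endothelial markers were lower, and 1 interferon gene and 1 macrophage marker higher, at an unadjusted p under 0.05. There Psmb8 went to -0.38 ± 0.18, Tap1 to -0.32 ± 0.16 and Irf7 to -0.33 ± 0.18, while C1qa lay at -0.33 ± 0.13. Camera at the preset correlation still called the interferon and macrophage lists there (adjusted p = 4.58e-04 and 0.00323). It did not call the endothelial list (adjusted p = 0.14), nor with the beta-actin difference (adjusted p = 0.0842). With 1 array left out, 5 interferon genes fell without vehicle 2 or dosed 1, 0 macrophage markers fell without vehicle 1 or dosed 5, and 1 fell without vehicle 2, vehicle 4, dosed 1 or dosed 4. The endothelial call ended without dosed 1 (adjusted p = 0.059) or dosed 5 (adjusted p = 0.0555), and 1 endothelial marker fell without vehicle 5.

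**Figure D3:**
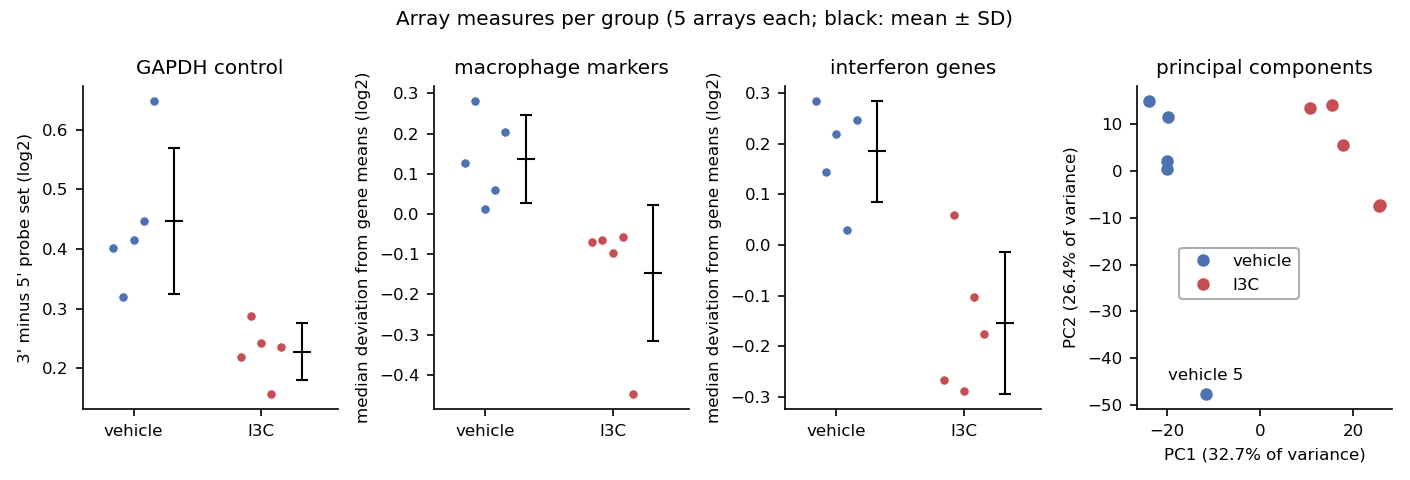
GAPDH 3' minus 5' difference, macrophage median and interferon median per array for 5 vehicle and 5 I3C arrays (vertical axes on the log2 scale; black marks give mean ± SD) and, at the right, the first and second principal components of all probe sets. The GAPDH difference has means of 0.45 and 0.23, the macrophage and interferon medians are lower in dosed arrays by 0.28 and 0.34, vehicle 5 lies at -47.8 on the second component, and the points of dosed 1 and dosed 4 overlap.

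Markers of the other cell types showed few changes. Hepatocyte markers were not called, with 1 of 18 rising and 0 falling (1 and 1 when adjusted over the list alone, camera adjusted p = 0.448), and Alb differed by 0.00 ± 0.05. Of 22 stellate cell and matrix markers 1 rose and 1 fell (1 and 4 when adjusted over the list alone), with Rgs5 at 1.33 ± 0.18 and Bgn at -0.36 ± 0.09. Bgn lost its call without vehicle 2, vehicle 3, vehicle 4, dosed 1, dosed 3, dosed 4 or dosed 5 (adjusted p up to 0.0952), 3 markers fell without vehicle 5, and with the GAPDH difference in the model the call of Rgs5 ended at 1.19 ± 0.30 (adjusted p = 0.0927) and Bgn went to -0.15 ± 0.13. That list was called as shifted down at a camera adjusted p of 0.0283, and not with an estimated correlation (adjusted p = 0.37) nor without vehicle 2, vehicle 5, dosed 1 or dosed 5 (adjusted p between 0.0519 and 0.09). The call also ended with the mean of a gene's probe sets (adjusted p = 0.0554), the GAPDH difference (adjusted p = 0.279) or the dap spike difference (adjusted p = 0.0503). The other cell type lists were not called by camera. They were cholangiocyte markers (0 of 13 rose and 0 fell, adjusted p = 0.413), lymphocyte markers (1 of 22 rose and 1 fell, adjusted p = 0.895) and neutrophil and mast cell markers (0 of 14 rose and 0 fell, adjusted p = 0.895). The lymphocyte list was called as shifted up with the GAPDH difference in the model (camera adjusted p = 0.018, against 0.427 to 0.977 under the alternatives fixed in advance), with 4 markers higher and 1 lower at an unadjusted p under 0.05. Erythroid markers (0 of 10 rose and 0 fell, adjusted p = 0.7) and markers of pancreas, adipose tissue and muscle (0 of 22 rose and 1 fell, adjusted p = 0.895) were not called either. When adjusted over the list alone 1 cholangiocyte marker rose, and the counts of the other 4 lists were the same. At an unadjusted p under 0.05, 1 cholangiocyte marker was higher and 1 lower, and 0 neutrophil, mast cell and erythroid markers passed. Gzma, the fallen lymphocyte marker (-0.47 ± 0.11), lost its call without vehicle 1, vehicle 2, vehicle 4, dosed 1, dosed 2, dosed 4 or dosed 5 (adjusted p up to 0.065), and lay at -0.66 ± 0.17 with the GAPDH difference (adjusted p = 0.0932). Without vehicle 3 or dosed 2, 1 cholangiocyte marker rose, and without dosed 5, 1 member of the last list rose. Its fallen member was Cpa1, a digestive carboxypeptidase, whose vehicle mean of 11.54 ± 0.41 (SD, n = 5) lay at the 97.6th percentile of probe sets.

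The remaining lists were not called by camera. Of 12 thyroid hormone responsive genes Me1 rose and Tbl1x fell, by 0.43 ± 0.08 (adjusted p = 0.686 for the list, 1 and 1 when adjusted over the list alone). With the mean of its probe sets the call of Tbl1x ended (-0.34, adjusted p = 0.222). Of 15 genes of tryptophan and NAD metabolism 3 rose and 3 fell (5 and 5 when adjusted over the list alone, list adjusted p = 0.988), with Aox1 at 0.54 ± 0.08 and Qprt at -0.53 ± 0.09. Of 28 acute phase and inflammation genes 2 rose and 0 fell, also when adjusted over the list alone (list adjusted p = 0.852). They were Orm1 (0.56 ± 0.11) and Crp (0.35 ± 0.07). Of 20 heme and iron genes 1 rose and 3 fell (4 and 3 when adjusted over the list alone, list adjusted p = 0.852): Alas1, the rate-limiting enzyme of heme synthesis, rose by 0.56 ± 0.11, and the iron exporter Slc40a1 fell by 0.52 ± 0.10. Of 24 retinoid genes 1 rose and 1 fell (2 and 4 when adjusted over the list alone, list adjusted p = 0.37), namely Aldh1a1 and Lrat. Of 17 oestrogen genes Cyp1b1 and Nr0b2 rose and 0 fell (2 and 1 when adjusted over the list alone, list adjusted p = 0.441). Of 19 circadian clock genes 0 rose and 0 fell by limma, also when adjusted over the list alone (list adjusted p = 0.895), and 2 were higher and 3 lower at an unadjusted p under 0.05. Without vehicle 5, 5 tryptophan and NAD genes, 3 retinoid genes and 2 thyroid hormone genes fell. Without dosed 2, 1 acute phase gene fell, without vehicle 4, 1 oestrogen gene fell, 2 heme and iron genes rose without vehicle 2 or vehicle 4, and 2 retinoid genes rose without vehicle 1 or dosed 3. In 10 lists, none of them called by camera, the median, mean and test differed in sign: PPAR alpha targets, male-predominant genes, thyroid hormone genes, tryptophan and NAD genes, acute phase genes, heme and iron genes, oestrogen genes, lymphocyte markers, neutrophil and mast cell markers, and the markers of pancreas, adipose tissue and muscle. With the GAPDH difference in the model the calls of Tbl1x (-0.34 ± 0.13), Aox1 (0.54 ± 0.13), Qprt (-0.31 ± 0.13), Orm1 (0.65 ± 0.18), Crp (0.43 ± 0.11) and Alas1 (0.52 ± 0.19) ended, and that of Slc40a1 held at -0.83 ± 0.13.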

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

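The comparisons of ATF4 targets with chaperones, of macrophage with endothelial markers and of interferon with macrophage genes, the covariate fits, and their split into interferon and macrophage genes were tests chosen after the result was seen.

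Single arrays lay far from the other 4 of their group, by Dixon's criterion, in 14 of 258 groups of 5 values tested, where chance marks about 1 in 20. Of these, 7 belong to vehicle 5. Its correlation with its own group was 0.988 (others 0.996 to 0.997), its second principal component -47.8 (others 0.395 to 15.1), its 3' minus 5' difference of the dap spike 1.73 (others 1.08 to 1.25) and its mean of poly-A spikes 7.38 (others 7.80 to 7.94). Also in vehicle 5, Rora was 7.56 (others 8.65 to 8.95), Slc40a1 10.83 (others 11.26 to 11.36) and Anxa4 8.15 (others 8.67 to 8.82). In this array 350 probe sets lay at least 2-fold from the mean of its group, 314 of them lower, against 30 to 76 in the other arrays.

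In dosed 5, Gstp1 was 11.75 (others 10.16 to 10.48) and Akr1b8 8.92 (others 7.69 to 7.85). Hal was 9.85 in dosed 1 (others 10.998 to 11.46), Angptl4 10.61 in dosed 2 (others 10.98 to 11.11) and Cyp2a1 13.08 in dosed 3 (others 13.24 to 13.29). Aldh3a1 was 4.68 in vehicle 3 (others 5.38 to 5.46) and Cyp17a1 9.54 in vehicle 4 (others 8.92 to 9.07).

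The first pattern weighed is the difference between the groups as a whole, with 914 genes changed. Chance is argued against for the counts of genes: of 100 splits of the arrays into 5 and 5, 1 gave as many probe sets (1487, highest other 1), 1 as many genes (914, highest other 1), 1 as many at least 2-fold (101, highest other 1) and 1 as many called lists (19, highest other 16). That 1 is the real split, so the share is the smallest these splits can give. The others mix dosed and vehicle arrays, which widens the spread within groups and lowers their counts of genes. Other splits called a median of 4 lists and 91 of 99 called some, so that a list call at the preset correlation is weaker evidence than the counts of genes. RNA quality was read from the GAPDH difference. With it in the model the median ratio of adjusted to unadjusted change was 0.941 over the 914 genes. The mean change went from 0.63 ± 0.02 (SE) to 0.61 ± 0.04. These genes were chosen for a small spread within groups, which favours a ratio near 1, and 0 probe sets were related to the covariate within groups. As far as a linear covariate can show, RNA quality is argued against as the whole cause only for the 190 genes that stayed called. Of the 724 calls that ended, 471 kept at least 75% of their change while the median SE rose from 0.0891 to 0.136 with a covariate that correlates with the group at -0.80, but 161 kept 50% to 75% and 92 kept less, among them Igfbp1 (1.20 ± 0.30 to 0.15 ± 0.35), so that a part played by RNA quality in single genes stays open.

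The second pattern is the rise of 7 genes of the stress and amino acid response list, set beside 16 chaperones and foldases of which 1 rose, Manf (0.29 ± 0.07, SE), with 0 rising without vehicle 2, vehicle 3, vehicle 4, dosed 2, dosed 3, dosed 4 or dosed 5, and 2 without vehicle 5. The contrast follows in part from how genes were assigned, since Manf is also 1 of the 7, and the co-chaperone Dnajb9 (0.82 ± 0.09), another of the 7, was not put among the chaperones. RNA quality is argued against as the whole cause only for the 4 of the 7 risen genes that stayed called with the covariate. Over the 7 genes the median ratio was 0.951, and the mean change was 1.37 ± 0.06 (SE) without and 1.41 ± 0.10 with the covariate. An ATF4 target programme cannot be told apart from a shift shared with the chaperones: 23 ATF4 targets whose values had not been looked at were shifted up (camera p = 0.0013, and p = 0.0124 with an estimated correlation, median 0.14), and so were the chaperones at the preset correlation (camera p = 0.0027, and p = 0.163 with an estimated correlation, median 0.09). The target list leaves out Asns, Trib3, Phgdh and Psat1, whose rises had been seen. It holds some cytosolic aminoacyl-tRNA synthetases, none of which rose, and not the 9 of 19 described below that did. The per-array median of the ATF4 targets minus that of the chaperones was -0.0062 ± 0.11 (SD, n = 5) in vehicle and -0.0034 ± 0.12 in dosed arrays (exact permutation p = 0.952, and at least 0.437 with 1 array left out), and of these targets 3 rose, with 2 rising without vehicle 3, dosed 2 or dosed 5, 5 without vehicle 5, and 1 with the GAPDH covariate.

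The third pattern is the lower level of interferon genes and macrophage markers. RNA quality cannot be told apart as the whole cause over the 12 fallen genes, with a median ratio of 0.92 and a mean change of 0.52 ± 0.08 (SE) without and 0.47 ± 0.14 with the covariate (0.50 ± 0.09 and 0.52 ± 0.21 without vehicle 5), since 0 stayed called by limma as the median SE rose from 0.114 to 0.176, although camera at the preset correlation still called both lists (adjusted p = 4.58e-04 and 0.00323). Over the 8 interferon genes the ratio was 0.747 and the mean change 0.58 ± 0.10 and 0.48 ± 0.17 (0.55 ± 0.11 and 0.52 ± 0.25 without vehicle 5), and over the 4 macrophage markers 1.06, with 0.40 ± 0.08 and 0.45 ± 0.15 (0.40 ± 0.10 and 0.53 ± 0.21 without vehicle 5). For these 4 markers too RNA quality cannot be told apart, since they were picked as fallen in these data and 0 stayed called with the covariate. A smaller share of all non-parenchymal cells and a change in macrophages cannot be told apart: the macrophage median minus the endothelial median was 0.06 ± 0.09 (SD, n = 5) in vehicle and -0.11 ± 0.15 in dosed arrays (exact permutation p = 0.0476), but p was above the threshold without vehicle 1, vehicle 2, vehicle 3, vehicle 5, dosed 2, dosed 3 or dosed 5, reaching 0.127. Nor can a lower interferon signal carried by macrophages alone be told apart from one in all cells, since the interferon median minus the macrophage median was 0.05 ± 0.14 (SD, n = 5) and -0.01 ± 0.21 (exact permutation p = 0.627), and an effect of I3C on these cells stays among the open explanations.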

How the results depend on the processing

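The covariate fits were tests chosen after the result was seen. All 914 changed genes kept their sign under every alternative that refitted them. The other variance model, the replicate block and the fit without moderation leave the size of each change as it was, so they could turn no sign. Of 101 named genes past the threshold, 79 kept call and direction under every alternative fixed in advance, 0 changed direction, 18 lost the call without at least 1 array, and 55 lost it with the GAPDH covariate, which turned 0 signs. Without variance moderation 896 probe sets and 594 genes were changed, at the stricter threshold of 0.01 646 and 437, with the GAPDH covariate 355 and 228, and with the beta-actin covariate 752 and 498. Both covariates move with the groups, which widens the SE, and a stricter threshold calls fewer by construction; for the fit without moderation the cause was not tested. With a size limit of 1.5-fold 301 genes passed, and with a test against 1.5-fold 50, as these limits set. With an estimated correlation 4 of 19 lists were called. The estimate was -0.0073 for the other P450 enzymes and -0.022 for the p53 targets, below the preset 0.01. A higher correlation between genes therefore did not end these calls. With an estimated correlation camera also takes its degrees of freedom from the arrays rather than from the genes, which raises p. Leaving out 1 array gave 1035 to 2085 probe sets, 651 to 1243 genes, 93 to 106 genes at least 2-fold and 15 to 19 lists. Array weights gave the highest gene count of any setting, 1343. With 1 array left out the highest came without vehicle 5, where 43.8% of changed genes were higher. Replicate numbers do not pair the samples: same-numbered arrays deviated with correlations of -0.03, 0.22, 0.09, -0.28 and -0.01, and 2 of 5 vehicle arrays correlated best with their own number. With the replicate block 1032 probe sets, 647 genes, 102 genes at least 2-fold and 19 lists were called. Dim probe sets are limited by background.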

Other observations

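The gene groups here were put together after results had been seen, some of them around members already known to have changed, and all of their counts and tests were chosen then. Of 19 cytosolic aminoacyl-tRNA synthetases 9 rose and 0 fell, with a median of 0.28 (camera p = 3.43e-07, and p = 0.0505 with an estimated correlation). Nars1, for asparagine, rose by 0.56 ± 0.08 (SE), Eprs1, for glutamate and proline, by 0.52 ± 0.07 and Gars1, for glycine, by 0.52 ± 0.08. Of 6 genes of serine and glycine synthesis 5 rose and 0 fell. Phgdh and Psat1, whose rises prompted the group, are 2 of them, so that the count does not test it. The others include Mthfd2 of mitochondrial folate metabolism (0.58 ± 0.08) and Psph, the last enzyme of serine synthesis (0.48 ± 0.10). With 1 array left out 6 synthetases rose without vehicle 1, dosed 2 or dosed 5. With the GAPDH covariate 0 synthetases passed limma, where Nars1 lay at 0.52, Eprs1 at 0.46 and Gars1 at 0.52, and 4 serine and glycine genes rose.

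Of 16 ligand-activated and stress-sensing transcription factors 6 rose and 1 fell, and 2 fell without vehicle 5. Nr1i2, which encodes PXR, was among the 9 that did not pass (0.03 ± 0.08, adjusted p = 0.924), as were Rxra, Keap1 and Arnt. Atf4, Nfe2l2 and Nr1h4 had been seen to change before the group was formed, so that no test of the group is given. Nr1i3, which encodes CAR, rose by 1.32 ± 0.20 (SE), Nfe2l2, which encodes NRF2, by 1.05 ± 0.10 and Ahr, the aryl hydrocarbon receptor, by 1.02 ± 0.13, and the bile acid receptor Nr1h4 fell by 0.54 ± 0.10. With the GAPDH covariate 3 rose and 1 fell, and the calls of Ahr (0.65, adjusted p = 0.118) and Nr1i3 (1.18, adjusted p = 0.13) ended. In the growth hormone and STAT5 pathway 3 of 11 genes fell and 0 rose (camera p = 0.0139, and p = 0.0769 with an estimated correlation), with 1 falling without vehicle 2 or dosed 4 and 5 without dosed 3. They were Igfals, which carries IGF1 in blood (-0.54 ± 0.11), Cish (-0.84 ± 0.19) and Cux2 (-0.57 ± 0.13). Some members, among them Cux2, also stand in fixed lists whose results had been seen, so the count and test of this group do not stand apart from those. Igfals went to -0.23 with the GAPDH covariate (adjusted p = 0.505), Cish lost its call without vehicle 2, dosed 2, dosed 4 or dosed 5 (adjusted p up to 0.0614), and Cux2 without vehicle 2, vehicle 3, vehicle 4, dosed 1 or dosed 4 (adjusted p up to 0.0647). With the GAPDH covariate 0 genes of this group fell, and the calls of Cish (-0.65, adjusted p = 0.363) and Cux2 (-0.58, adjusted p = 0.249) ended too.

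Some probe sets annotated to several genes moved by large amounts and are given without a single gene name. A probe set shared by 2 CEACAM adhesion genes rose by 4.03 ± 0.15 (SE), and both probe sets shared by 8 genes of the UGT1A locus rose, by 0.95 ± 0.10 and 0.63 ± 0.07.

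Class II histocompatibility probe sets took far apart levels within a group. RT1-Ba was 5.35 in vehicle 1 and 6.43 in vehicle 5, and 9.24 to 10.84 in the other 8 arrays. RT1-Bb was 5.80 in vehicle 2, 5.59 in vehicle 3 and 5.08 in dosed 1, and 8.66 to 10.12 in the other 7 arrays.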
